A study of Homo sapiens with 12 samples.

How the data were processed

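RNA from IMR-90 human lung fibroblasts was measured on 12 Affymetrix arrays in 4 groups of 3 biological replicates: young and senescent cells at 20% oxygen, and young and old nonsenescent cells at 3% oxygen. The labels give population doublings of 30 for both young groups, 48 for the senescent and 53 for the old cells, and describe separate incubators for the 2 oxygen levels, with RNA extraction in TRIzol. The labels call the groups matched by age; the doublings of the 2 late groups differ as given here.

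The authors made the deposited values with RMA, whose version is not stated. The deposited values are taken as log2 values, centred on the median of each probe set over the 12 arrays; the base of the logarithm is not stated, and log2 is assumed from the use of RMA. The table holds 54675 probe sets and 0 missing values. Every probe set has a median of 0 within a tolerance of 1e-06 (largest absolute median 5e-07), values run from -6.17 to 4.96, and array medians from -0.02 to 0.05. Because of the centring no absolute level, and so no signal over background, can be read. The planned collapse to the probe set with the highest mean and the planned filter on dim genes could therefore not be run. The mean of all probe sets that name the gene, which had been an alternative, became the main choice, and a filter on flat genes (SD over the 12 arrays below the median of all genes) was added.

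Of the probe sets, 62 are controls, 41091 name 1 gene, 1801 several genes and 11721 others none. Those naming 1 gene were matched by Entrez identifier to current symbols (41037 matched), and their mean was taken per gene. This gave 19775 genes, 9252 with 1 probe set and 10523 with several (31839 probe sets).

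Group means were fitted over all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with contrasts for senescent minus young cells at 20% oxygen, old minus young cells at 3%, young cells at 3% minus 20%, old cells at 3% minus senescent cells at 20%, and the interaction (the first contrast minus the second). Tests were two-sided, adjusted by Benjamini-Hochberg over all genes within a contrast, and called at an adjusted p under 0.05; adjusted p values of genes in the text are those of limma. Gene lists, 38 in number, were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 38 lists within a contrast. Beside it, camera with a correlation estimated from the data and fry were run; fry tests whether a list's genes move, on balance, one way, and does not compare the list with other genes. With each list the text gives the members called over all genes and those called when adjusted over the list alone. Some genes belong to several lists, so the results of lists that share members are not independent.

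The groups, contrasts, tests, thresholds, gene lists and the rule for naming genes were chosen before the data were examined. The rule names, per contrast, the 10 largest rises and the 10 largest falls among called genes whose replicates do not overlap between the groups (for the interaction, called genes alone), up to 4 members with the largest absolute change per list described, and a fixed panel of 20 genes, of which 18 were measured; the other 2, and some list members, are not reported here. The text names part of the genes that the rule allows. The lists of immediate-early genes, pregnancy-specific glycoproteins and keratin-associated proteins were added after the results were seen.

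Alternatives tried were an intensity trend with robust eBayes, no collapse of probe sets, quantile normalization again, centring of each array on its median, a fit of the 2 groups compared alone, array quality weights, the replicate number as a replicate block, a minimum absolute log2 change of 1, an adjusted p under 0.01, and leaving out each array in turn. Chosen after seeing the data were the filter on flat genes, the probe set with the largest SD per gene, and 2 covariates per array: its score on the first axis of the within-group deviations of probe sets that name no gene (the array-wide factor), and the 3' minus 5' difference of the ACTB control probe sets (RNA quality). Also added was a replicate block in the senescent and old arrays alone: the labels do not say what the replicate numbers mean, but the deviations from the group means of the 3 same-numbered pairs of these 2 groups all correlated over 0.1 (0.129, 0.519 and 0.669), which was the case for no other 2 groups. The 6 arrays of 2 groups can be split in 10 ways, and for the interaction 100 splits of the 12 arrays were drawn with a fixed seed; the residuals of a fit without the interaction were permuted as often. The fit was tested on simulated data in which known genes change: at log2 changes of 0.5, 1 and 2 it recovered 28.4%, 83.6% and 100% of them with independent noise, and 34.3%, 94.0% and 100% with noise shared along an axis. Probe sets that name several genes or none were left out of the tests, and raw array files were not used here.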

Results

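RNA of IMR-90, a line of human lung fibroblasts with a finite number of divisions in culture, was hybridised to 12 Affymetrix arrays. The arrays fall into 4 groups of 3: young cells at 20% oxygen (population doubling 30), senescent cells at 20% oxygen (population doubling 48), young cells at 3% oxygen (population doubling 30) and old but nonsenescent cells at 3% oxygen (population doubling 53). The series asks how expression changes with age and senescence at the 2 oxygen levels. Cells of the 2 oxygen levels grew in separate incubators, so oxygen and incubator go together in every comparison between them. The replicate numbers and the word biological in the labels are the only evidence that the 3 arrays of a group come from separate cultures. Each value is a log2 signal relative to the median of its probe set over the 12 arrays, so changes between groups can be read and absolute levels cannot. Values after ± are standard errors of the log2 change unless SD is named, with n = 3 arrays per group; this number of arrays limits the precision. Of 19775 genes tested, 2474 differed between senescent and young cells at 20% oxygen, 344 between old and young cells at 3% oxygen, 2333 between young cells at 3% and 20% oxygen, and 2176 between old cells at 3% and senescent cells at 20% oxygen (adjusted p under 0.05).

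Senescent cells at 20% oxygen differed from young cells at the same oxygen level in targets of the hypoxia-inducible factors, which were higher in the senescent cells. The neuronal-type enolase ENO2 rose by 2.63 ± 0.11 on the log2 scale (6.19-fold, adjusted p = 1.81e-08), the MYC antagonist MXI1 by 2.49 ± 0.09 (5.63-fold), and the mitophagy receptor BNIP3 by 2.37 ± 0.10 (5.15-fold). NDRG1 rose 5.15-fold and DDIT4, an inhibitor of mTORC1 signalling, 4.13-fold. Of 37 measured targets, 29 were higher and 1 lower over all genes, and 30 and 1 adjusted over the list alone. The list median was 0.89 (adjusted p = 1.36e-32, adjusted p = 0.00394 with an estimated correlation). Glycolysis genes followed: 13 of 17 were higher and 1 lower, with the same counts adjusted over the list alone. Their median log2 change was 0.59 (adjusted p = 7.81e-12, adjusted p = 0.00435 with an estimated correlation). The glucose transporter SLC2A1 rose 2.67-fold, PGK1 2.68-fold and ALDOC 2.04-fold; these genes and ENO2 belong to both lists, so the results of the lists are not independent. The mean of the hypoxia-inducible factor targets was -0.79 ± 0.02 in young cells at 20% oxygen, 0.22 ± 0.05 in senescent cells, 0.04 ± 0.03 in young cells at 3% oxygen and 0.06 ± 0.09 in old cells at 3% oxygen (SD, n = 3), so the young cells at 20% oxygen were the group apart. PDK1, a kinase that inhibits the pyruvate dehydrogenase of the mitochondria, rose by 1.21 ± 0.15, but its 3 probe sets gave 2.08, 1.40 and 0.14. VEGFA, another target, was not called (0.20 ± 0.11, adjusted p = 0.369), and ADM rose by 0.54 ± 0.09 (adjusted p = 0.00186).

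**Figure D1:**
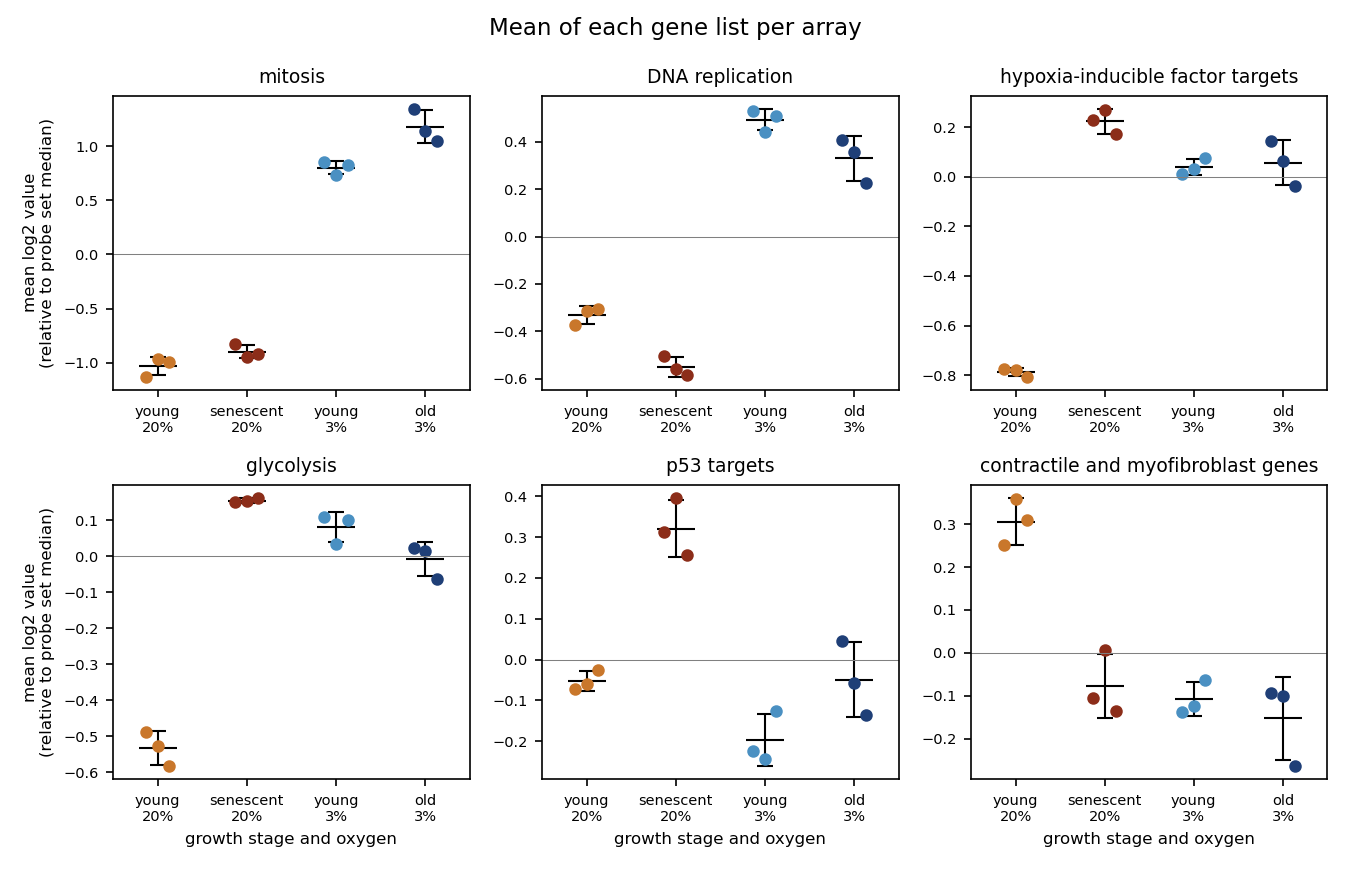
Mean log2 value of 6 gene lists per array (relative to the probe set median), by growth stage and oxygen level; points are arrays, horizontal marks group means and bars SD (n = 3). Mitosis genes averaged -1.03 and -0.90 in the groups at 20% oxygen against 0.80 and 1.18 at 3%, while hypoxia-inducible factor targets averaged -0.79 in young cells at 20% oxygen and between 0.04 and 0.22 in the other groups.

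The cyclin-dependent kinase inhibitor CDKN1A (p21) rose 3.39-fold in senescent cells (1.76 ± 0.11, adjusted p = 6.17e-07). Other p53 targets rose with it, among them the ribonucleotide reductase subunit RRM2B (2.32-fold), the DNA damage sensor DDB2 (2.27-fold) and CCNG1 (1.9-fold). In all, 9 of 27 measured p53 targets were higher and none lower, and 11 and 2 adjusted over the list alone. As a list they had a median log2 change of 0.25 (adjusted p = 2.7e-06, adjusted p = 0.13 with an estimated correlation). CDKN2A (p16 and ARF) rose by 0.47 ± 0.13 (adjusted p = 0.0348), a call that ended without any 1 of the 6 arrays compared: adjusted p = 0.119, 0.104 and 0.0665 without young replicate 1, 2 and 3, and 0.101, 0.0949 and 0.0737 without senescent replicate 1, 2 and 3. Its 3 probe sets gave 0.81, 0.58 and 0.01, and the 2 probe sets of CDKN2B gave 0.10 and -0.75. The CDK inhibitors as a list were not called (2 of 6 higher, 1 lower, adjusted p = 0.0506).

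LMNB1, the lamin whose loss marks senescence, fell by 0.62 on the log2 scale (SE 0.12, 1.53-fold lower, adjusted p = 0.00445); after quantile normalization the change was -0.44 and not called (adjusted p = 0.155). The Polycomb methyltransferase EZH2 fell 2.14-fold. Of 44 DNA replication genes, 11 were lower and none higher, and 13 and 1 adjusted over the list alone; the helicase subunit MCM6 fell 2.13-fold and cyclin E2 (CCNE2) 1.95-fold. The median over the list was -0.17 (adjusted p = 1.82e-04, adjusted p = 0.215 with an estimated correlation). The mitosis genes as a list were not lower. MKI67 (0.16 ± 0.14, adjusted p = 0.635) and CCNA2 (0.05 ± 0.12, adjusted p = 0.894) were not called, and their group means were low in both groups at 20% oxygen: -0.99 ± 0.16 and -0.83 ± 0.15 for MKI67 in young and senescent cells (SD, n = 3), against 0.65 ± 0.08 and 0.85 ± 0.26 in young and old cells at 3%. With array quality weights, which called 6203 genes here in place of 2474, MKI67 did pass (adjusted p = 0.00266), and so did VEGFA (adjusted p = 0.0235). Of 46 mitosis genes, 8 were higher in senescent cells and 1, AURKA, lower (1.7-fold), and 10 and 2 adjusted over the list alone. For the whole list the median was 0.16 (adjusted p = 0.0246, adjusted p = 0.571 with an estimated correlation). That list was no longer called without young replicate 1 (adjusted p = 0.114) or senescent replicate 1 (adjusted p = 0.175).

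Secreted factors moved both ways. The collagenase MMP1 rose 3.47-fold (1.80 ± 0.12), the stromelysin MMP3 1.91-fold and the growth factor binding protein IGFBP3 2.21-fold, while the cytokine IL6 fell 2.48-fold (-1.31 ± 0.12, adjusted p = 1.64e-05), the neutrophil chemokine CXCL8 4.35-fold (-2.12 ± 0.11) and LIF 5.14-fold. IGFBP3 stood at -1.20 to -0.92 on the young arrays at 20% oxygen, at 0.08 to 0.15 in senescent cells and at 0.29 to 0.43 in young cells at 3%. Of 47 measured members of the secretory phenotype of senescent fibroblasts, 7 were higher and 12 lower, and 9 and 13 adjusted over the list alone; the list was not called (median log2 -0.03, adjusted p = 0.108).

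**Figure D2:**
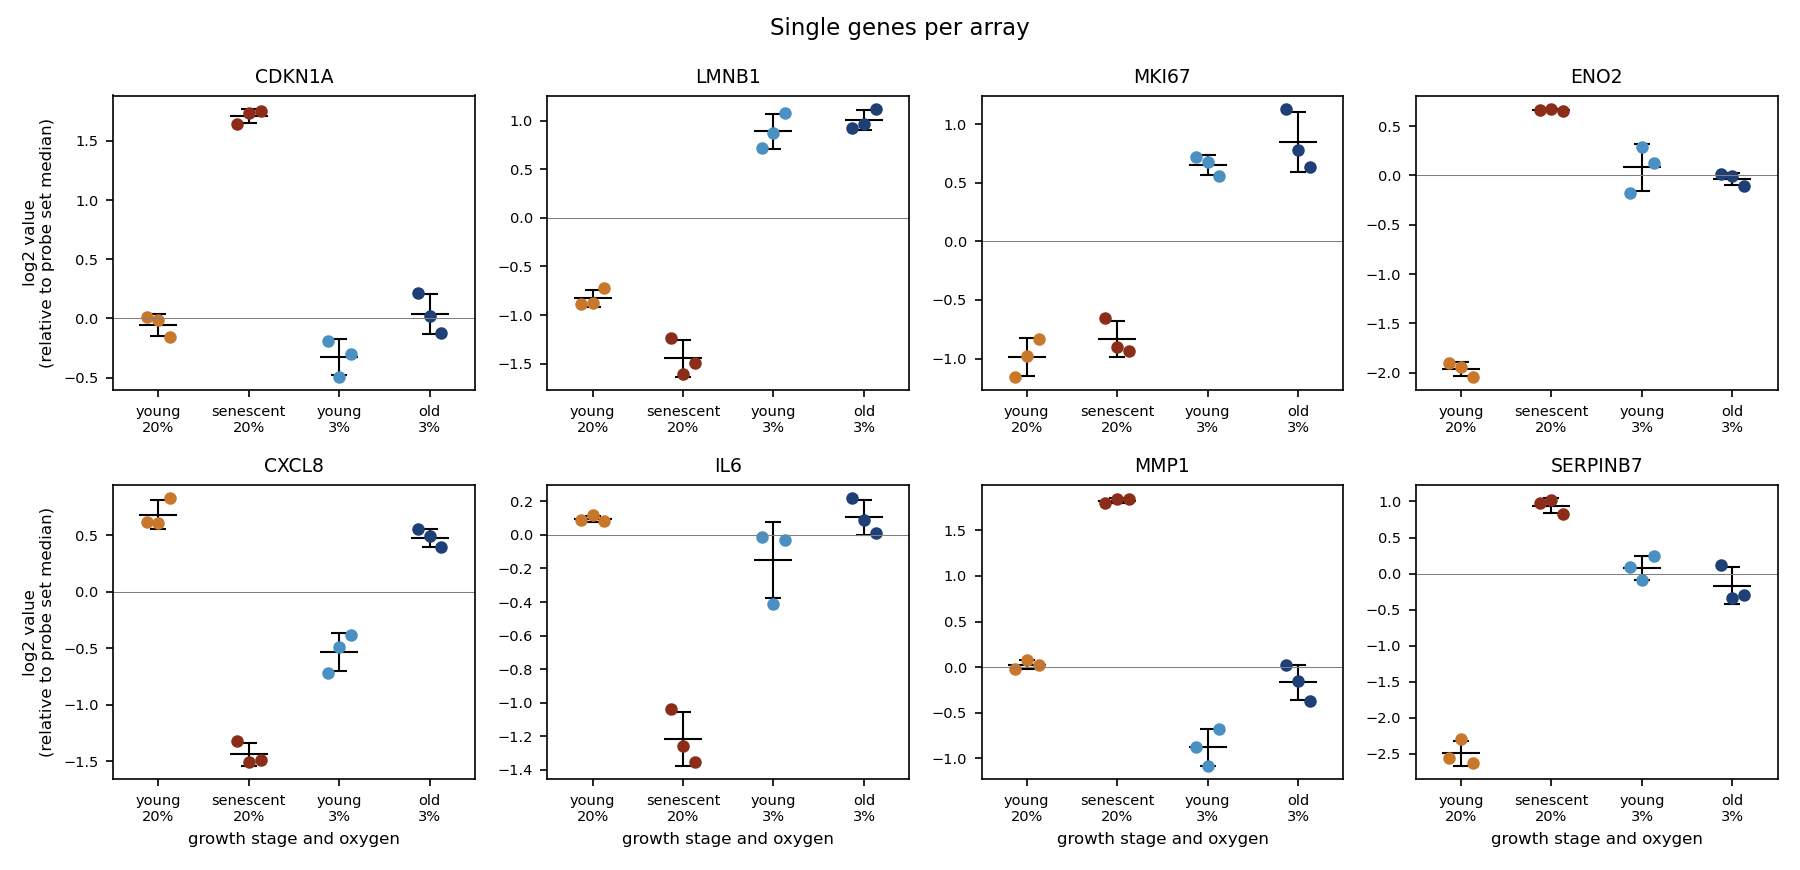
Log2 value of 8 genes per array (relative to the probe set median), by growth stage and oxygen level; points are arrays, horizontal marks group means and bars SD (n = 3). CDKN1A and SERPINB7 stand highest in senescent cells, CXCL8 is lowest there (its change from young cells is -2.12), and MKI67 is low in both groups at 20% oxygen.

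Contractile genes, TGF-beta targets and some matrix proteins were lower in senescent than in young cells at 20% oxygen. The contractile list averaged 0.31 in these young cells and -0.08 in senescent cells. At 3% oxygen it averaged -0.11 in young and -0.15 in old cells. In the same order, matrix proteins other than collagens averaged 0.33, -0.01, -0.02 and -0.14. In both lists the young cells at 20% oxygen were thus the group apart. TGF-beta targets (0.06, -0.34, -0.07 and 0.16) were lowest in senescent cells. Of 20 contractile and myofibroblast genes, 11 were lower and 1 higher, and 12 and 1 adjusted over the list alone, with the cardiac actin ACTC1 2.74-fold and LMOD1 1.72-fold lower. Over the list, the median change was -0.40 (adjusted p = 4.39e-07, adjusted p = 0.0835 with an estimated correlation). Among TGF-beta targets 10 of 21 were lower and 3 higher, and 11 and 4 adjusted over the list alone; ID1 fell 4.25-fold, the inhibitory SMAD7 3.17-fold and ID3 2.69-fold. This list had a median log2 change of -0.26 (adjusted p = 2.47e-04, adjusted p = 0.242 with an estimated correlation). Matrix proteins other than collagens had 14 of 36 members lower and 3 higher, and 16 and 3 adjusted over the list alone, with tenascin C (TNC) 4.08-fold, MFAP4 4.08-fold and lumican (LUM) 2.69-fold lower. All members together had a median of -0.13 (adjusted p = 5.69e-05, adjusted p = 0.215 with an estimated correlation). The enzymes that hydroxylate and crosslink collagen went the other way: 12 of 16 were higher and 1 lower, also adjusted over the list alone, led by lysyl oxidase (LOX, 2.85-fold), LOXL3 (2.81-fold) and PLOD2 (2.43-fold). The list median was 0.56 (adjusted p = 9.76e-09, adjusted p = 0.0511 with an estimated correlation). LOX, P4HA1 and P4HA2 also belong to the hypoxia-inducible factor list, so the results of these lists are not independent. Collagens (0 higher and 6 lower of 24, adjusted p = 0.219), matrix-degrading proteases (5 higher and 5 lower of 24, adjusted p = 0.981) and secreted Wnt and BMP regulators (3 higher and 7 lower of 28, adjusted p = 0.165) were not called as lists, though the ligand WNT2 fell 5.84-fold.

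Stress programs divided. Endoplasmic reticulum stress and ATF4 targets had 11 of 33 higher and 3 lower, and 17 and 4 adjusted over the list alone, among them VLDLR (3.11-fold) and the serine synthesis enzyme PSAT1 (2.62-fold). Their median log2 change was 0.30 (adjusted p = 3.14e-05, adjusted p = 0.281 with an estimated correlation). Heat shock genes had 6 of 16 lower and 1 higher, and 8 and 1 adjusted over the list alone, with the chaperones HSPH1 2.6-fold and DNAJA1 2.1-fold lower. As a list they had a median log2 change of -0.23 (adjusted p = 0.00304, adjusted p = 0.281 with an estimated correlation). For NRF2 targets 8 of 26 were lower and 2 higher, and 10 and 3 adjusted over the list alone: EPHX1 fell 2.39-fold and NQO1 2.05-fold while the cystine transporter SLC7A11 rose 1.76-fold. The median over the list was -0.12 (adjusted p = 0.00312, adjusted p = 0.317 with an estimated correlation). All metallothioneins but 1 of 7 were higher, and all 7 adjusted over the list alone. For the whole list the median was 0.70 (adjusted p = 7.66e-07, adjusted p = 0.13 with an estimated correlation). Lysosomal genes had 9 of 43 higher and 3 lower, and 12 and 3 adjusted over the list alone, with ATP6AP1 2.06-fold and FUCA1 1.6-fold higher. Over the list, the median change was 0.17 (adjusted p = 8.12e-04, adjusted p = 0.295 with an estimated correlation). Class I antigen presentation had 7 of 18 higher and 1 lower, the same adjusted over the list alone (median log2 0.17, adjusted p = 0.0143, adjusted p = 0.317 with an estimated correlation), and replication-dependent histones 1 of 29 higher and none lower (median log2 0.15, adjusted p = 0.00664, adjusted p = 0.317 with an estimated correlation). Group means of the metallothionein, lysosomal, antigen presentation and histone lists were instead highest in senescent cells. Metallothionein, HLA and histone genes are close relatives whose probe sets can read each other, so single members of these families are uncertain.

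Homologous recombination and Fanconi repair genes (3 of 22 lower, 4 adjusted over the list alone; median log2 -0.19, adjusted p = 0.0105, adjusted p = 0.317 with an estimated correlation) and the chromatin and lamina genes known to fall in senescence (8 of 23 lower, 9 lower and 3 higher adjusted over the list alone; median log2 -0.11, adjusted p = 0.00664, adjusted p = 0.281 with an estimated correlation) were lower. After quantile normalization neither was called (adjusted p = 0.0591 and 0.12). Cholesterol synthesis genes were lower too (5 of 24, also adjusted over the list alone; median log2 -0.15, adjusted p = 0.0108, adjusted p = 0.345 with an estimated correlation), but not called without senescent replicate 3 (adjusted p = 0.0535) or after quantile normalization (adjusted p = 0.0553). Growth factor receptors and ligands were called lower with a mean of -0.19 and a median of 0.000723, so that median and test differ in sign (1 higher and 6 lower of 24, 2 and 7 adjusted over the list alone; adjusted p = 0.0271, adjusted p = 0.281 with an estimated correlation, adjusted p = 0.0553 after quantile normalization and 0.0559 with RNA quality as a covariate). Lung fibroblast identity genes were called lower (1 higher and 5 lower of 18, 4 and 7 adjusted over the list alone; median log2 -0.04, adjusted p = 0.0262, adjusted p = 0.281 with an estimated correlation), but not after quantile normalization (adjusted p = 0.0591) or with RNA quality as a covariate (0.0567); DCN fell 2.09-fold. Interferon-stimulated genes (3 higher and 2 lower of 39, adjusted p = 0.781), oxidative phosphorylation (adjusted p = 0.129), other antioxidant enzymes (adjusted p = 0.187), ribosomal proteins (adjusted p = 0.976), telomere proteins (adjusted p = 0.66) and sirtuins with other ageing regulators (adjusted p = 0.921) were not called. Neither were the markers of epithelial (adjusted p = 0.168), endothelial (0.976), immune (0.317), pericyte and smooth muscle (0.90), adipocyte and chondro-osteogenic (0.921), and mesothelial and neural cells (0.921).

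By size, the protease inhibitor SERPINB7 (3.43 ± 0.14, 10.8-fold) and MAMDC2 (9.65-fold) rose most in senescent cells. SERPINB7 stood at -2.62 to -2.29 on the young arrays at 20% oxygen, at 0.82 to 1.02 in senescent cells and at -0.33 to 0.24 at 3%. Much of its rise thus lay in low values of the young cells at 20% oxygen. MAMDC2 stood at 2.26 to 2.47 in senescent cells and at -1.03 to 0.39 on all other arrays. Besides hypoxia-inducible factor targets, the 10 largest rises also held MOK (6.03-fold), MAP3K7CL (4.49-fold) and the pregnancy-specific glycoprotein PSG3 (4.23-fold). SHISA3 fell most (-4.39 ± 0.21, 20.9-fold), then FGL2 (20.5-fold), the secretory granule chaperone SCG5 (10.1-fold), the chemoattractant RARRES2 (10.1-fold), the collagen regulator CTHRC1 (9.75-fold), TMEM176A (9.28-fold), WFDC1 (8.95-fold), and the immediate-early transcription factors EGR3 (8.77-fold) and FOS (7.87-fold). For RARRES2, TMEM176A, EGR3 and FOS the young arrays at 20% oxygen were the ones apart. TMEM176A stood at 3.01 to 3.30 there and at -0.33 to 0.13 on all other arrays. RARRES2 stood at 3.01 to 3.30 and at -0.58 to 0.13, and FOS at 2.32 to 2.70 and at -0.62 to 0.86. CTHRC1 and WFDC1 were instead low in senescent cells alone, CTHRC1 at -3.32 to -3.19 against -0.21 to 0.47 on all other arrays. In total 923 genes were higher and 1551 lower, 102 and 270 of them at least 2-fold. Of the 38 lists, 10 were called higher and 11 lower. With an estimated correlation between genes, the hypoxia-inducible factor and glycolysis lists alone were called.

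At 3% oxygen, old cells differed from young cells in far fewer genes: 194 were higher and 150 lower, of which 46 and 34 at least 2-fold. The steroid dehydrogenase HSD17B2 rose 6.13-fold (2.62 ± 0.17, adjusted p = 4.74e-06), CCDC68 5.86-fold, the Notch ligand DNER 4.97-fold, the endothelin receptor EDNRB 4.54-fold and the cytokine IL24 4.19-fold. The urea transporter SLC14A1 fell 7.9-fold (-2.98 ± 0.11), reelin (RELN) 4.3-fold, the planar polarity gene VANGL2 4.2-fold, the adhesion molecule VCAM1 3.89-fold and the chemokine CCL2 3.36-fold. ADAMTS5 rose 3.63-fold over the mean of 4 probe sets, of which 1 gave -0.11 and the others 2.09 to 3.09, and HEPH fell on 1 of its 2 probe sets alone (-3.77 and -0.22). The count of changed genes rested in part on single arrays: it was 187 without old replicate 2, 200 without old replicate 1, 227 without young replicate 2 and 228 without young replicate 1. A fit of the 2 groups alone called 124. Such a fit has fewer residual degrees of freedom and also takes the spread per gene from these 2 groups alone. For senescent against young cells at 20% oxygen it called 2534 genes in place of 2474, so fewer degrees of freedom alone need not lower the count. After quantile normalization 48.3% of the called genes were higher, against 56.4% in the values as deposited, so which direction held the majority depended on the scaling.

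At 3% oxygen the arrest marker CDKN1A (0.37 ± 0.11, adjusted p = 0.156), LMNB1 (0.11 ± 0.12, adjusted p = 0.636), MKI67 (0.20 ± 0.14, adjusted p = 0.474) and IL6 (0.26 ± 0.12, adjusted p = 0.362) were not called. CXCL8 rose 2.01-fold (1.01 ± 0.11, adjusted p = 3.23e-04) and MMP1 1.63-fold (adjusted p = 0.0080, adjusted p = 0.11 in a fit of the 2 groups alone). Mitosis genes were higher in the old cells: 7 of 46 and none lower, and 18 adjusted over the list alone. This list had a median log2 change of 0.38 (adjusted p = 5.95e-13, adjusted p = 0.439 with an estimated correlation). DNA replication genes were lower, 3 of 44, and 4 adjusted over the list alone, with MCM6 1.73-fold lower. All members together had a median of -0.14 (adjusted p = 1.37e-05, adjusted p = 0.439 with an estimated correlation). The hypoxia-inducible factor targets were not called (1 of 37 higher, adjusted p = 0.394).

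Matrix genes moved in part. Among proteases and their inhibitors 2 of 24 were higher and 1 lower, and 8 and 1 adjusted over the list alone. The list median was 0.24 (adjusted p = 0.00538, adjusted p = 0.45 with an estimated correlation). COL5A3 rose 2.77-fold and COL4A5 2.02-fold (adjusted p = 0.0515 in a fit of the 2 groups alone); 4 of 24 collagens were higher and 1 lower, and 8 and 1 adjusted over the list alone, a call that ended without old replicate 1 (adjusted p = 0.0572), old replicate 3 (0.148), young replicate 3 (0.216) or with a replicate block (0.065). Their median log2 change was 0.08 (adjusted p = 0.0486, adjusted p = 0.659 with an estimated correlation). Other matrix proteins had 8 of 36 lower and 1 higher, and 10 and 2 adjusted over the list alone (median log2 -0.05, adjusted p = 0.0112, adjusted p = 0.659 with an estimated correlation; adjusted p = 0.0542 and a median turned to 0.01 without young replicate 2, and 0.0539 with a median of 0.00384 with RNA quality as a covariate). The contractile gene SYNPO2 fell 2.59-fold, and the ligands WNT2 and BMP2 rose 3.31-fold and 3.27-fold.

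Another 4 lists were called at 3% oxygen and lost without single arrays. TGF-beta targets (2 higher and 2 lower of 21, 8 and 2 adjusted over the list alone; median log2 0.23, adjusted p = 0.0418, adjusted p = 0.659 with an estimated correlation) were not called without old replicate 1 (adjusted p = 0.0982), old replicate 3 (0.0586) or young replicate 2 (0.0542). For lysosomal genes (1 of 43 higher, 3 adjusted over the list alone; median log2 0.17, adjusted p = 0.0112, adjusted p = 0.659 with an estimated correlation) this held without old replicate 1 (adjusted p = 0.0554). The p53 targets (1 higher and 1 lower of 27, the same adjusted over the list alone; median log2 0.19, adjusted p = 0.0418, adjusted p = 0.659 with an estimated correlation) were not called without old replicate 1 (adjusted p = 0.157), old replicate 3 (0.0848), young replicate 2 (0.154), or with the array-wide factor (0.0778) or RNA quality (0.0737) as a covariate. Glycolysis was called lower although limma called no single member of 17, and none adjusted over the list alone; the call ended without old replicate 3 (adjusted p = 0.0931), young replicate 3 (0.0583) or with the array-wide factor as a covariate (0.0557). As a list they had a median log2 change of -0.11 (adjusted p = 0.027, adjusted p = 0.45 with an estimated correlation). In all 6 lists were called higher and 3 lower, and 5 without old replicate 1 or without old replicate 3. With an estimated correlation none of the 38 passed (4 at an unadjusted p under 0.05), and 5 passed by fry.

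**Figure D3:**
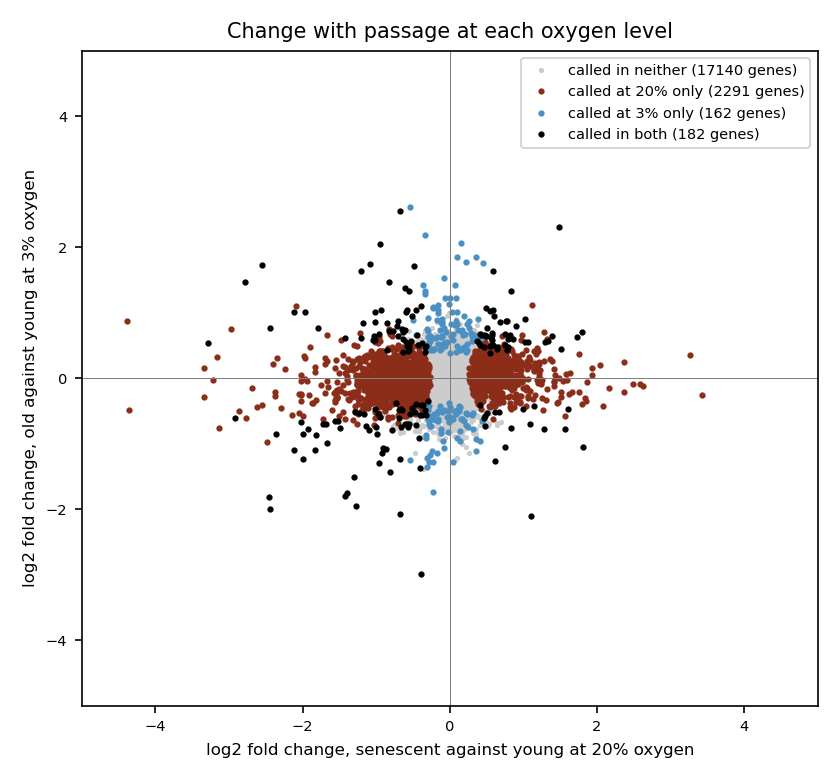
Log2 fold change of each of 19775 genes, senescent against young cells at 20% oxygen (horizontal) and old against young cells at 3% oxygen (vertical), coloured by the comparisons in which the gene was called at adjusted p under 0.05. Of these genes, 2291 were called at 20% oxygen and not at 3%, 162 at 3% and not at 20%, and 182 in both.

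Whether the change with passage differed between the oxygen levels was tested as an interaction: the log2 change at 20% oxygen minus that at 3%. It passed for 1273 genes, 408 with a positive and 865 with a negative difference. Of the 2474 genes called at 20% oxygen 1080 passed this test (43.7%), and of the 344 called at 3% oxygen 197 did (57.3%). CDKN1A had a difference of 1.39 ± 0.16 (adjusted p = 1.61e-04), CXCL8 of -3.13 ± 0.15 and IL6 of -1.57 ± 0.17. SERPINB7 (3.68 ± 0.20), MAMDC2, ENO2, MOK, MXI1 and BNIP3 had large positive differences, with a rise at 20% oxygen and no call at 3%. RELN (3.21 ± 0.12) and CPA4 (2.86 ± 0.17) rose at 20% and fell at 3% oxygen, and SLC14A1 (2.59 ± 0.15) was lower at both (-0.39, adjusted p = 0.0298, at 20% and -2.98 at 3%). SHISA3 (-5.26 ± 0.30), WNT2 (-4.27 ± 0.27) and TRPA1 (-4.25 ± 0.19) had the largest negative differences; WNT2 and TRPA1 fell at 20% and rose at 3% oxygen. LMNB1 passed with a difference of -0.73 ± 0.17 (adjusted p = 0.0231), but not after quantile normalization (adjusted p = 0.398), nor with RNA quality as a covariate (0.0521) or array quality weights (0.0665), nor without senescent replicate 2 (adjusted p = 0.0545), senescent replicate 3 (0.0603), young replicate 3 at 20% (0.0621) or young replicate 2 at 3% (0.0509).

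As lists, hypoxia-inducible factor targets had a positive difference in 24 of 37 genes and a negative one in none, and in 28 and 2 adjusted over the list alone (median log2 0.79, adjusted p = 4.02e-31, adjusted p = 0.00236 with an estimated correlation), and glycolysis genes in 11 of 17 and none, and in 13 and 1 adjusted over the list alone (median log2 0.70, adjusted p = 4.39e-14, adjusted p = 0.00236 with an estimated correlation). Both held with an estimated correlation, the only 2 of the 13 called lists that did. The list of collagen crosslinking enzymes shares LOX, P4HA1 and P4HA2 with the hypoxia-inducible factor list. Collagen crosslinking enzymes (7 of 16 positive, 10 and 1 negative adjusted over the list alone; median log2 0.56, adjusted p = 8.88e-09, adjusted p = 0.0504 with an estimated correlation), p53 targets (5 of 27, 6 adjusted over the list alone; median log2 0.13, adjusted p = 0.00385, adjusted p = 0.421 with an estimated correlation) and metallothioneins (1 of 7, 6 adjusted over the list alone; median log2 0.52, adjusted p = 2.15e-04, adjusted p = 0.365 with an estimated correlation) also differed upwards. TGF-beta targets (8 of 21 negative and 3 positive, 13 and 3 adjusted over the list alone; median log2 -0.51, adjusted p = 1.85e-05, adjusted p = 0.281 with an estimated correlation), contractile genes (3 of 20 negative and 1 positive, 6 and 2 adjusted over the list alone; median log2 -0.35, adjusted p = 0.00277, adjusted p = 0.365 with an estimated correlation) and NRF2 targets (6 of 26 negative and 1 positive, 6 and 2 adjusted over the list alone; median log2 -0.22, adjusted p = 0.00533, adjusted p = 0.511 with an estimated correlation) differed downwards.

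The comparison of young cells asks what the oxygen level itself changes. Young cells at 3% oxygen had higher mitosis transcripts than young cells of the same population doubling at 20% oxygen. The kinetochore gene NUF2 rose 7.53-fold (2.91 ± 0.14, adjusted p = 4.29e-08), the kinesin KIF20A 7.45-fold, the checkpoint kinase BUB1B 6.45-fold and HMMR 6.56-fold; MKI67 was 3.11-fold, CCNA2 3.9-fold and LMNB1 3.29-fold higher. Of 46 mitosis genes 42 were higher and none lower, and 43 adjusted over the list alone. The median over the list was 1.98 (adjusted p = 1.32e-64, adjusted p = 0.00224 with an estimated correlation). Of 4 probe sets for MKI67, 1 gave 0.50 and the others 1.95 to 2.13; the 2 of HMGB2 gave 2.15 and -0.42. DNA replication genes had 31 of 44 higher and 1 lower, and 34 and 1 adjusted over the list alone, with POLE2 4.07-fold and RRM2 3.66-fold higher. For the whole list the median was 0.89 (adjusted p = 3.35e-28, adjusted p = 0.00224 with an estimated correlation). In homologous recombination and Fanconi repair 15 of 22 were higher, and 16 adjusted over the list alone, with RAD51AP1 4.56-fold higher. Over the list, the median change was 0.68 (adjusted p = 8.51e-13, adjusted p = 0.0277 with an estimated correlation). Chromatin and lamina genes had 17 of 23 higher, and 19 and 1 lower adjusted over the list alone, with the condensin NCAPG 4.92-fold higher. This list had a median log2 change of 0.81 (adjusted p = 3.26e-20, adjusted p = 0.00386 with an estimated correlation).

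Hypoxia-inducible factor targets were higher at 3% oxygen, as 26 of 37 against 2 lower, and 31 and 2 adjusted over the list alone: NDRG1 rose 5.4-fold, BNIP3 4.21-fold, ENO2 4.12-fold and DDIT4 6.32-fold. All members together had a median of 0.60 (adjusted p = 1.18e-29, adjusted p = 0.00224 with an estimated correlation). Glycolysis genes rose with them, 13 of 17 with 1 lower, and 14 and 1 adjusted over the list alone. The list median was 0.55 (adjusted p = 9.79e-13, adjusted p = 0.00224 with an estimated correlation). The comparison shares its 3 young arrays at 20% oxygen with that of senescent and young cells, so the 2 rises of these lists are not independent. Endoplasmic reticulum stress and ATF4 targets had 11 of 33 higher and 1 lower, and 14 and 2 adjusted over the list alone (median log2 0.20, adjusted p = 1.02e-07, adjusted p = 0.134 with an estimated correlation), with the serine synthesis enzymes PSAT1 2.59-fold and PHGDH 2.44-fold higher, and collagen crosslinking enzymes 6 of 16 higher, and 7 and 1 lower adjusted over the list alone (median log2 0.17, adjusted p = 3.97e-04, adjusted p = 0.131 with an estimated correlation).

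Several secreted, contractile and cholesterol synthesis genes were lower at 3% oxygen. The pattern-recognition protein PTX3 fell 11.4-fold (-3.51 ± 0.12), VCAM1 10.5-fold, CYTL1 16.6-fold, RARRES2 10.1-fold and the cytokine TSLP 8.22-fold. Of 47 genes of the secretory phenotype 18 were lower and 4 higher, and 22 and 8 adjusted over the list alone, with CCL2 6.76-fold, TNFRSF11B 7.25-fold and CXCL8 2.32-fold lower; IL6 was not called (-0.25 ± 0.12, adjusted p = 0.253). The median of these 47 genes was -0.25 (adjusted p = 0.00142, adjusted p = 0.132 with an estimated correlation). IL1B (1.68 ± 0.18, adjusted p = 3.95e-05) and PTGS2 (1.98 ± 0.19, adjusted p = 1.76e-05), chosen for this comparison after their values were seen, were higher at 3%. Proteases and inhibitors had 9 of 24 lower, and 13 and 1 higher adjusted over the list alone, with ADAMTS1 4.43-fold lower. As a list they had a median log2 change of -0.32 (adjusted p = 1.49e-05, adjusted p = 0.0749 with an estimated correlation). Contractile genes had 9 of 20 lower, and 12 adjusted over the list alone. The median over the list was -0.38 (adjusted p = 4.89e-07, adjusted p = 0.0556 with an estimated correlation). Cholesterol synthesis genes had 8 of 24 lower, and 12 adjusted over the list alone, with MSMO1 3.28-fold and HMGCS1 2.99-fold lower. For the whole list the median was -0.31 (adjusted p = 1.85e-07, adjusted p = 0.11 with an estimated correlation). NRF2 targets had 9 of 26 lower, and 12 adjusted over the list alone, and the mitochondrial superoxide dismutase SOD2 fell 2.00-fold. Over the list, the median change was -0.19 (adjusted p = 1.36e-05, adjusted p = 0.175 with an estimated correlation). Other matrix proteins (14 of 36 lower and 4 higher, 16 and 5 adjusted over the list alone; median log2 -0.22, adjusted p = 0.00282, adjusted p = 0.266 with an estimated correlation) and growth factors with their receptors (9 of 24 lower and 1 higher, 12 and 2 adjusted over the list alone; median log2 -0.22, adjusted p = 0.00139, adjusted p = 0.124 with an estimated correlation) were lower too. CDKN1A (-0.27 ± 0.11, adjusted p = 0.152) was not called, except with array quality weights (adjusted p = 0.018). GDF15 was lower at 3% oxygen (-0.73 ± 0.20, adjusted p = 0.0324), but not called without young replicate 1 (0.114) or 3 (0.104) at 20%, without young replicate 1 (0.129) or 2 (0.0997) at 3%, or with a replicate block (0.0589); it was not called with passage at 20% (adjusted p = 0.67) or 3% oxygen (0.631). HMOX1 was not called in any of the 5 contrasts (adjusted p = 0.484 to 0.976). In total 980 genes were higher and 1353 lower, 239 and 220 at least 2-fold, and 9 of the 38 lists were called higher and 11 lower. With an estimated correlation 6 of the higher lists and 0 of the lower ones were called. Metallothioneins, called higher, and replication-dependent histones, p53 targets, lysosomal and heat shock genes, called lower, each lost the call without some single arrays.

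Old cells at 3% oxygen compared with senescent cells at 20% oxygen addressed what separates nonsenescent from senescent cells at ages that the labels call matched. The groups differ in oxygen, in state and in population doubling (53 against 48), and these cannot be separated here. NDC80 was 11.6-fold higher in the old cells (3.54 ± 0.16, adjusted p = 3.05e-08), KIF18B 10.6-fold, LMNB1 5.47-fold and EZH2 5.27-fold, and CDKN1A was 3.18-fold lower (-1.67 ± 0.11). Of 46 mitosis genes 45 were higher, also adjusted over the list alone (median log2 2.27, adjusted p = 3.21e-77, adjusted p = 0.00259 with an estimated correlation). Of 44 DNA replication genes 31 were higher, and 34 adjusted over the list alone (median log2 0.91, adjusted p = 1.72e-30, adjusted p = 0.00259 with an estimated correlation). Of 22 homologous recombination and Fanconi genes 16 were higher, and 18 adjusted over the list alone (median log2 0.89, adjusted p = 1.27e-18, adjusted p = 0.013 with an estimated correlation), and of 23 chromatin and lamina genes 17 were, and 20 and 1 lower adjusted over the list alone (median log2 1.08, adjusted p = 7.6e-24, adjusted p = 0.00359 with an estimated correlation). These 4 lists were the ones called with an estimated correlation. On 2 of its 3 probe sets CDKN2A was lower (-1.94 and -1.60, against 0.07 on the third).

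The prostaglandin synthase PTGS2 was 16.1-fold higher in the old cells (4.01 ± 0.19), CTHRC1 12.8-fold, IL1B 7.95-fold, CXCL8 3.77-fold and IL6 2.5-fold, whereas VCAM1 was 16.9-fold lower (-4.08 ± 0.13), SLC14A1 9.04-fold, CCL2 8.64-fold and MMP1 3.98-fold. The secretory phenotype as a list was not called (6 of 47 higher, 11 lower, adjusted p = 0.057). TGF-beta targets had 8 of 21 higher and 2 lower, and 9 and 2 adjusted over the list alone, with ID1 7.53-fold higher. This list had a median log2 change of 0.19 (adjusted p = 1.22e-04, adjusted p = 0.249 with an estimated correlation). The p53 targets had 10 of 27 lower, and 11 adjusted over the list alone (median log2 -0.19, adjusted p = 2.99e-07, adjusted p = 0.104 with an estimated correlation), and lysosomal genes 11 of 43 lower and 1 higher, and 15 and 3 adjusted over the list alone (median log2 -0.19, adjusted p = 1.22e-04, adjusted p = 0.253 with an estimated correlation). Hypoxia-inducible factor targets had 12 of 37 lower and 3 higher, and 13 and 4 adjusted over the list alone, although the old cells were those at 3% oxygen; EGLN3 was 2.22-fold higher and ALDOC 1.84-fold lower. All members together had a median of -0.15 (adjusted p = 0.00181, adjusted p = 0.253 with an estimated correlation). Collagen crosslinking enzymes (7 of 16 lower and 1 higher, 8 and 2 adjusted over the list alone; median log2 -0.28, adjusted p = 4.02e-04, adjusted p = 0.224 with an estimated correlation) and cholesterol synthesis genes (6 of 24 lower and 2 higher, 8 and 2 adjusted over the list alone; median log2 -0.21, adjusted p = 3.88e-04, adjusted p = 0.253 with an estimated correlation) were lower. GDF15 was lower in the old cells (-0.75 ± 0.20, adjusted p = 0.0297), but not called without senescent replicate 2 (0.113), without old replicate 1 (0.0555), 2 (0.0619) or 3 (0.0994), with a replicate block over the 12 arrays (0.0551) or in a fit of the 2 groups alone (0.0531). In total 1304 genes were higher and 872 lower, 319 and 151 at least 2-fold, with 7 lists called higher and 12 lower. With an estimated correlation 4 of the higher lists and 0 of the lower ones were called. Among the lower lists, glycolysis, other antioxidant enzymes and matrix-degrading proteases lost the call without some single arrays.

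The changes with passage at the 2 oxygen levels overlapped: 46 genes were called higher in both, where independent calls would give 9.05, and 64 lower in both (11.8 if independent). Opposite calls also exceeded independence, with 18 genes higher at 20% and lower at 3% oxygen (7.0 if independent) and 54 lower at 20% and higher at 3% (15.2 if independent). All contrasts take 1 estimate of the spread per gene from the 12 arrays, so genes of small spread are more easily called in both. This holds for either direction, so an excess over independence need not mean a shared change. The count of 110 genes in the same direction was 62 without old replicate 2, 69 without young replicate 3 at 3%, 70 without senescent replicate 1, 71 without young replicate 1 at 20% and 73 without old replicate 1. Across genes, which are not independent replicates, the 2 sets of log2 changes had a Pearson r of 0.105 and a Spearman rho of 0.0957. The comparisons of 3% with 20% oxygen, in young cells and between old and senescent cells, overlapped more. Here 493 genes were higher at 3% in both (64.6 if independent) and 320 lower in both (59.7). Opposite calls numbered 47 and 105 (43.2 and 89.2 if independent). Across genes the Pearson r was 0.408 and the Spearman rho 0.122. Old and senescent cells also differ in state and population doubling, so this overlap cannot be put down to oxygen alone.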

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

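Among the tests in this part, those of the array-wide factor and of batches marked by replicate numbers were chosen only after the results were seen. The results listed first are those whose change with passage differed between 20% and 3% oxygen in a test of the difference itself, given as the log2 change at 20% minus that at 3%.

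The difference was positive in 408 genes and negative in 865. Positive values were 3.68 for SERPINB7, 3.21 for RELN, 2.91 for MAMDC2, 2.86 for CPA4, 2.75 for ENO2, 2.68 for MOK, 2.59 for SLC14A1, 2.58 for MXI1, 2.57 for BNIP3 and 2.50 for PSG3. Negative values were -5.26 for SHISA3, -4.27 for WNT2, -4.25 for TRPA1, -3.87 for FGL2, -3.82 for CTHRC1, -3.73 for FOS, -3.49 for WFDC1, -3.49 for RARRES2, -3.23 for CCDC68 and -3.21 for PRKAR2B. Of the genes fixed in advance, CDKN1A had 1.39, IL6 -1.57, CXCL8 -3.13, MMP1 1.09, IGFBP3 1.57 and ADM 0.64.

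For another 4 of those genes the call ended without single arrays and in other alternatives. LMNB1 had -0.73; its adjusted p was 0.0545 without senescent replicate 2, 0.0603 without senescent replicate 3, 0.0621 without young replicate 3 at 20% oxygen and 0.0509 without young replicate 2 at 3%, 0.398 after quantile normalization, 0.0521 with RNA quality as a covariate and 0.0665 with array quality weights. SOD2 had -0.51; its adjusted p was 0.0551 and 0.0534 without senescent replicate 1 and 2, and 0.0726 and 0.0513 without young replicate 1 and 2 at 20% oxygen, 0.0939 after quantile normalization, 0.0664 with the largest-SD probe set and 0.0571 without flat genes. MMP3 had 1.02 and was called without senescent replicate 2 or young replicate 2 at 20% oxygen, but without any other array its adjusted p was 0.0535 to 0.107, and it was 0.0575 with trend and robust eBayes, 0.0527 with arrays centred on their medians, 0.062 with a replicate block and 0.114 with RNA quality as a covariate. PDK1 had 0.79 and was called without young replicate 3 at 20% oxygen or old replicate 1, but without any other array its adjusted p was 0.0524 to 0.11, and it was 0.0542 with trend and robust eBayes and 0.0676 with a replicate block.

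List medians of the difference were 0.79 for hypoxia-inducible factor targets, 0.70 for glycolysis, 0.56 for collagen crosslinking and prolyl hydroxylation, 0.52 for metallothioneins, 0.13 for p53 targets, 0.12 for endoplasmic reticulum stress and ATF4 targets, -0.22 for NRF2 targets, -0.35 for contractile and myofibroblast genes and -0.51 for TGF-beta targets. With an estimated correlation 2 of the 13 lists were called, hypoxia-inducible factor targets and glycolysis; the other 11 had an adjusted p of 0.0504 to 0.646. Another 4 lists, all among those 11, also lost their call without single arrays. Mitosis genes had -0.13 (adjusted p = 0.131 without old replicate 1, 0.17 without senescent replicate 2, 0.0888 and 0.0833 without young replicate 2 at 20% and 3% oxygen, 0.0699 with RNA quality as a covariate, and 0.997 with a median of 0.09 after quantile normalization). Chromatin and nuclear lamina genes had -0.10 (adjusted p = 0.0632 and 0.0536 without old replicate 1 and 3, 0.134 without senescent replicate 2, 0.0819 and 0.0646 without young replicate 2 at 20% and 3% oxygen, 0.0646 without young replicate 3 at 3%, and 0.423 with a median of 0.01 after quantile normalization; without young replicate 2 at 3% the median was -0.01). Collagens had -0.13 (adjusted p = 0.0628 without senescent replicate 2, 0.0542 without young replicate 2 at 20% oxygen and 0.0646 without young replicate 3 at 3%). Lung fibroblast identity had -0.11 (adjusted p = 0.0714 and 0.0805 without old replicate 1 and 3, 0.121 without senescent replicate 2, 0.0888 and 0.14 without young replicate 2 at 20% and 3%, 0.0646 without young replicate 3 at 3%, 0.0636 with a replicate block, 0.0633 with arrays centred on their medians, 0.0963 after quantile normalization and 0.107 with RNA quality as a covariate).

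Mitosis genes were low in both groups at 20% oxygen, young cells included, with a list median of 1.98 between young cells at 3% and 20% oxygen. With the array-wide factor or RNA quality as a covariate the median stayed at 2.03. The effect of a covariate comes from arrays of the same group, which differed little (SD of the list mean 0.06 to 0.15). A technical difference that goes with the group is thus not excluded. Slower growth or a denser culture of the young cells at 20% oxygen when harvested may explain the pattern as well as oxygen itself, and the incubator goes with the oxygen level; none of these could be tested here.

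Hypoxia-inducible factor targets were higher in senescent than in young cells of the same 20% setting, by a median of 0.89. The setting was the same in both groups by design, so it cannot by itself make the difference. The median was 0.89 with the array-wide factor as a covariate and 0.92 with RNA quality. Here, too, the effect of a covariate comes from arrays of the same group, which differed little (SD of the list mean 0.02 to 0.09). A technical difference that goes with the group is thus not excluded. The young cells at 20% oxygen were the group apart, so the pattern may come from oxygen at the cell surface, from culture density or medium at harvest, or from senescence. None of these was tested, and the arrays of these young cells also enter the comparison with young cells at 3% oxygen.

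Arrays of 1 group differed along a shared axis that carried 49.8% of the within-group variance, and 48.5% of it in probe sets that name no gene (r = 0.998 between the 2 axes over arrays, both from the same arrays). Batches marked by the replicate numbers stay open. The deviations of same-numbered arrays correlated over 0.1 in 9 of 18 pairs, from -0.59 to 0.67 with a mean r of -0.03. All 3 pairs of senescent and old arrays were among these 9, which was seen only on looking through all pairs of groups. Over the 12 arrays, as deviations within groups, the axis and the ACTB 3' minus 5' difference had a Pearson r of 0.27 (permutation p = 0.404, the only relation computed in this family) and a Spearman rho of 0.42 (permutation p = 0.177). Without the 2 arrays farthest from the median of the ACTB difference r was 0.871, so RNA quality stays open although r met the bound of 0.3 set against it beforehand; that reading was tightened after the result was seen. Young replicate 2 at 3% oxygen had the largest 3' minus 5' difference of the 12 arrays, in the control probe sets of ACTB (0.71) and of GAPDH (0.36). Several calls given above ended without this array, and whether RNA quality was the reason was not tested. Other technical sources such as hybridisation or scan batches were not tested, and no biological explanation was.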

How the results depend on the processing

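The filter on flat genes, the probe set with the largest SD, the replicate block in the senescent and old arrays and the 2 covariates were chosen after the data were seen. The filter on dim genes was not run, because the centred values hold no level; for the same reason signal over background is unknown. The mean of all probe sets, planned as an alternative, is the main choice.

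Probe sets without collapse give no single value per gene, and the fit of the 2 groups alone covers 483 calls of named genes, of which 431 held. Of all 597 calls of named genes, none changed direction in the alternatives computed for it. Calls held in 591 with array quality weights, 589 with arrays centred on their medians, 583 with the array-wide factor, 566 with trend and robust eBayes, 563 with a replicate block, 558 each after quantile normalization and with the RNA quality covariate, and 537 with the largest-SD probe set. Leaving out 1 array ended 32 to 54 of the 321 to 390 calls it bears on, depending on the array. Of 67 named genes not called, array quality weights called 16. Over all 4 groups, same-numbered arrays did not all deviate together (5 of 12 correlated best with an array of their own number), and a replicate block over the 12 arrays gave 2028 genes for old against senescent cells in place of 2176. A block in the senescent and old arrays alone gave 2370 and the same 19 lists, and 139 of 141 calls of named genes held there.

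Genes at an absolute log2 change of at least 1 numbered 372 in senescent against young cells at 20% oxygen, 80 in old against young at 3%, 459 in young cells at 3% against 20%, 470 in old at 3% against senescent cells and 452 in the interaction. At an adjusted p under 0.01 they numbered 1477, 162, 1412, 1305 and 624. The same-direction overlaps were then 44 for passage and 521 for the 2 comparisons of 3% with 20% oxygen. A stricter threshold lowers counts by construction. Array quality weights gave 6203 genes for senescent against young cells, 4137 for old against senescent cells and 2684 for the interaction, and probe sets without collapse 1936 genes in the interaction; the cause was not tested. The fit of the 2 groups alone gave 124 genes at 3% oxygen, and 2534 for senescent against young cells at 20%. It has fewer residual degrees of freedom and also takes the spread per gene from the 2 groups alone. Leaving out 1 array gave 187 to 423 genes there and 62 to 108 in the passage overlap, with fewer arrays, and 5 to 11 lists. Without flat genes the median change of all genes was 0.107 at 3% oxygen, -0.115 between oxygen levels in young cells and -0.117 in the interaction.

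An estimated correlation allows for genes of a list varying together. With it camera called 2, 0 (4 at an unadjusted p under 0.05), 6, 4 and 2 lists in the same order, in place of 21, 9, 20, 19 and 13. In that order fry, which tests another question, called 25, 5, 27, 23 and 17 lists. Of these, 20, 3, 20, 19 and 11 were also called by camera at the preset correlation. Of the 82 list calls, 14 held with an estimated correlation, 71 after quantile normalization, 81 with centred arrays and 79 with a replicate block.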

Other observations

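The tests of the 3 gene families in this part were chosen after FOS, PSG3 and members of the keratin-associated family were seen among the largest changes; the splits of the arrays were planned, and the test of the interaction on residuals was chosen after the splits were seen.

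Some immediate-early genes, which respond to serum or stress within minutes, were lower in senescent than in young cells at 20% oxygen. FOS fell 7.87-fold, EGR3 8.77-fold, ZFP36 3.54-fold, FOSB 2.9-fold and IER2 2.38-fold, while IER5 rose 1.34-fold. Of 29 measured immediate-early genes 12 were lower, 1 was higher and the others were not called, with a median of -0.29; the list missed the threshold set for it (camera p = 0.0673 with an estimated correlation, by limma), so a shared fall stays open. In young cells at 3% against 20% oxygen 13 were lower and 2 higher, against the same young arrays at 20%. In old against young cells at 3% oxygen, other arrays, 6 were lower and 2 higher, with a median of -0.03 (camera p = 0.196 with an estimated correlation). Handling of the young cells at 20% oxygen before lysis, such as a change of medium, may raise such genes in the 2 comparisons that share these arrays, but not in the one at 3% oxygen, and a real difference in growth signalling may too; the values do not separate them.

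Pregnancy-specific glycoproteins, placental genes of 1 cluster, rose in senescent cells: 8 of 9 measured members were higher, with a median of 1.56 (camera p = 0.00112 with an estimated correlation, by limma). PSG3 rose 4.23-fold, PSG5 3.6-fold, PSG9 3.06-fold and PSG7 3.04-fold. In young cells at 3% against the same young arrays at 20% oxygen 4 of the 9 were higher and none lower, with a median of 0.48 (camera p = 0.0278 with an estimated correlation), so low values in those young arrays may be part of the rise. In old against young cells at 3% oxygen 3 were lower and none higher, with a median of -0.42, and the median of the difference between the oxygen levels was 1.85. The members are so alike in sequence that probe sets of 1 may read another. Their median pairwise correlation over the 12 arrays was 0.76, between the bounds set beforehand for a single shared signal (above 0.8) and against it (under 0.5), so how many members changed stays open.

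Of 13 measured keratin-associated genes of 1 cluster, KRTAP4-12 alone was lower in senescent cells (-2.78), and 4 were lower in old cells at 3% than in senescent cells at 20% oxygen, KRTAP1-5 the most (-3.74). These genes, too, are close relatives.

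Splits of the 6 arrays of 2 groups into 3 and 3 number 10, too few for a share under 0.05. The real split was the 1 of 10 with the most called genes in each comparison. Every other split mixes the 2 groups, so a large difference between them adds to the spread within its parts and lowers its adjusted count. The counts of the other splits therefore do not show what chance alone would give. Real counts were 2474, 344, 2333 and 2176 genes in the 4 comparisons of 2 groups, and by limma the highest of the other splits was 0 in each (at an unadjusted p under 0.05: 1485, 4527, 1191 and 4165 genes). At that unadjusted level the real splits gave 4297, 2815, 4549 and 3979, so for old against young cells at 3% oxygen, and for old against senescent cells, another split of the arrays had more, which points to a structure of the samples other than the groups. For old against senescent cells, whose same-numbered arrays deviated together, the split with 4165 parts 1 of the 3 pairs; the other splits that part all 3 pairs, as the real one does, gave 0 genes (at most 247 at an unadjusted p under 0.05) and at most 11 lists. For lists the real counts were 21, 9, 20 and 19, against at most 12, 6, 15 and 14 in the other splits, again 1 of 10 each.

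For the interaction, 2 of 100 splits of the 12 arrays, the real one included, gave as many called genes (1273 in the real one, at most 1920 in another). For its lists 30 of 100 splits gave as many (13 in the real one, at most 20 in another). Such splits mix the oxygen and passage changes, so they do not test the interaction by itself. The residuals of a fit in which oxygen and passage only add up were therefore permuted over the arrays. As many genes came up in 3 of 100 orders, the real one included (at most 2458 in another), and as many lists in 6 of 100 (at most 14 in another). This treats the 12 arrays as exchangeable. Same-numbered senescent and old arrays deviated together, which was found on looking through all pairs of groups and may itself be chance. Whether additive changes with chance could give these numbers therefore stays open.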
